A study of Eisenia fetida with 4 samples.

How the data were processed

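Total RNA pooled from adult, juvenile and cocoon Eisenia fetida was labelled with Cy3 as cRNA after linear amplification, per the labels' protocols, and hybridised to 2 arrays of 1 custom Agilent test design. The series title calls the design a sense one. Of the 4 test designs named for the study, the other designs are not analysed here. The titles give each scan its array and its PMT gain, 400 or 500, and the gain in each file header was the same as in its title. Samples were grouped by gain, with the array number as the replicate. Nothing in the labels ties an array to an animal, so p-values measure only technical spread.

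Per the file headers, the slides were scanned on a GenePix scanner at 532 nm with 5 micron pixels and quantified by GenePix Pro 6.1.0.4 with local feature background and no normalization. The deposited foreground and background columns are pixel intensity per spot on a linear scale, not normalized. The deposited saturation column is the percent of a spot's pixels at the scanner ceiling, and the deposited signal-to-noise column is a score that GenePix computes per spot, both per the file headers. Spots had a median of 120 foreground pixels and of 13 background pixels, and 0 spots carried a quality mark against them. The deposited series matrix holds intensity values equal to median foreground minus local background in all 243504 rows of each scan, when matched by the spot's reference number. It is therefore linear, with no centring.

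Signal over background was taken as the measure of depth. Target probes had a median foreground of 62 on both arrays at gain 400 against a background of 43, and of 212 and 214 at gain 500 against 131. Precision was limited by the number of arrays, and exact Clopper-Pearson intervals of shares cover counting error only.

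Detection was called where the median foreground exceeded the background median + 2 background SD. The alternatives were + 3 SD, a threshold at the mean + 3 SD of the negative controls' background-subtracted signal, and detection on at least 1 array. For agreement between arrays and the test between gains, foreground and background medians of all spots were corrected with limma's normexp at an offset of 50, control spots were left out, and the target probes were quantile normalised on the log2 scale. Other settings used no correction, plain subtraction, median centring, no normalization, pixel means or the series matrix. The gain effect was the median log2 difference of background-subtracted intensity over probes detected in both scans of an array and saturated in neither. A spot was saturated where its median foreground reached 65535, with 60000 and the pixel mean as alternatives.

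The test between gains was limma's lmFit and eBayes with a trend of the variance on intensity, the array as a block, and Benjamini-Hochberg adjustment at 0.05. The block was set before the data were examined, as were the tests, the alternatives and the rule for named probes. The pairing of scans comes from the titles. Scans of the same array deviated together, with a correlation across probes of 0.143 over all target probes and 0.750 over those detected in all 4 scans. The fit left 1 residual degree of freedom per probe and limma estimated no variation between probes beyond the trend, so probes of like intensity were given the same variance. The same step was tested on simulated scans of 241399 probes for the gain comparison. It recovered 92% of 100 probes changed by 0.58 log2 and 100% of those changed by 1. It called 1 of 42842 unchanged probes of like brightness, with 200 calls in all, so some calls were unchanged probes outside that brightness. The simulated scans had noise of the same spread for every probe, no scanner ceiling and no spots that jumped in a single scan. They therefore do not test calls among saturated or jumping spots. No probes near the background were changed, so recovery among dim probes was not tested either. The search for a step along the probe numbers was tested on a simulated series of 240000 probes whose detected share fell from 28% to 6%, and missed the true place by 43 probes. For a fall from 28% to 25% it missed by 4019 probes, and on a series with no change its scaled step was 0.690.

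Named probes were the 10 brightest unsaturated at gain 400, the 5 largest rises and 5 largest falls between gains among calls with the same sign on both arrays, and the 5 detected probes with the largest difference between arrays with the same sign at both gains. A probe counted as detected for the last list where any scan detected it, and the list was ranked by the mean difference over gains. Because identifiers carry no gene names here, only a few members of each list are printed. TA3-032447 was named after its values had been seen. The gene lists of the rule could not be applied without gene names. The planned comparisons of probes of 1 target and of probe lengths were not run, because the columns used here give no target or length for the target probes.

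Tiles of 20 by 27 spots were used for position, with probes detected in all 4 scans and saturated in none. The tiles, the step along the probe numbers, a foreground-only detection rule and a count over probes up to the step were added after the data had been seen. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.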

Results

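The data came from a test of candidate oligonucleotide probes for the earthworm Eisenia fetida, a compost-dwelling annelid. A single pool of total RNA from adults, juveniles and cocoons was labelled with the dye Cy3 and hybridised to 2 arrays of a test design whose title gives the sense orientation. Each array was scanned at photomultiplier (PMT) gains of 400 and 500, which gave 4 scans. The 2 arrays were technical replicates of 1 RNA pool, and the 2 scans of an array read the same hybridised molecules. The design therefore held no comparison between animals, life stages or treatments, and every SD given with n = 2 is the spread between 2 arrays. Each array carried 243504 spots, of which 241399 were target probes with distinct identifiers, 602 were negative controls and 1503 were other controls. The files do not pair the target identifiers with genes, so probes are given by identifier.

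The question the design put first was which of the candidate probes gave signal with earthworm RNA. At gain 400, 61715 target probes (25.6%) were detected on both arrays, and at gain 500 59083 (24.5%) were. A probe counted as detected where its median foreground exceeded the local background median by more than 2 background SD. Across all 4 scans 55075 target probes (22.8%) were detected every time, and 151566 (62.8%) were detected in no scan. The 602 negative control spots, which share 1 control name, gave 3 and 5 detected spots on arrays 1 and 2 at gain 400. At gain 500 they gave 4 and 2, and none was detected on both arrays at either gain. The highest of these shares was 0.831%, with an exact Clopper-Pearson interval of 0.270% to 1.93% that covers counting error only. Spots of 1 control name do not give a false-detection rate for the varied target probes.

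Per scan, 29.8% ± 0.704 of target probes (SD, n = 2) were detected at gain 400 and 28.2% ± 0.306 (SD, n = 2) at gain 500. The share was lower at the higher gain on both arrays, by −1.34 percentage points on array 1 and −1.90 on array 2, with a mean of −1.62 ± 0.399 (SD, n = 2). An exact paired sign-flip permutation test over the 2 arrays gave a two-sided p of 0.5, the smallest that 2 arrays allow, so the difference could not pass a threshold of 0.05. Of the probes detected at a gain on both arrays, 6640 were detected so only at gain 400 and 4008 only at gain 500. With a threshold taken from the negative controls in place of the local background, array 1 had the higher share at gain 500, by 0.266 points, and array 2 had the lower one, by −0.839 points. A foreground-only rule was added after the data had been seen. It detected 92498 probes (38.3%) on both arrays at gain 400 and 93444 (38.7%) at gain 500. For detection on both arrays the order of the gains thus turned, and both shares lay above the main rule's 25.6% and 24.5%. Per scan, the share at gain 500 differed by 1.43 points on array 1 and by −1.63 on array 2. Under this rule 1 and 4 of 602 negative control spots were detected on arrays 1 and 2 at each gain, and 0 on both arrays.

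The detected probes were not spread evenly over the identifiers. Up to probe TA3-217456, 60302 of 217456 probes (27.7%, exact interval 27.5% to 27.9%) were detected on both arrays at gain 400. From TA3-217457 to TA3-241399, 1413 of 23943 (5.90%, interval 5.61% to 6.21%) were. In bins of 2500 consecutive numbers the share lay between 21.4% and 35.6% before the step and between 4.72% and 6.96% after it. The 4.72% was in the last bin, which held only 1399 numbers. The bin that holds the step, left out of these ranges, had 35.8%. The 2156 probes just before the step, from TA3-215301 on, had a share of 39.2%. At gain 500 the shares before and after the step were 26.6% and 5.44%. The size of the step, scaled by the spread of the series, was 21.97, and the highest value in 100 shuffled orders of the same probes was 1.89. Among the probes up to the step, the search found a further, smaller change after number 95783, at 5.78, so lying above the shuffled orders was not particular to the first step. The intervals cover counting error only, and the step was found by looking along the numbers.

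**Figure D1:**
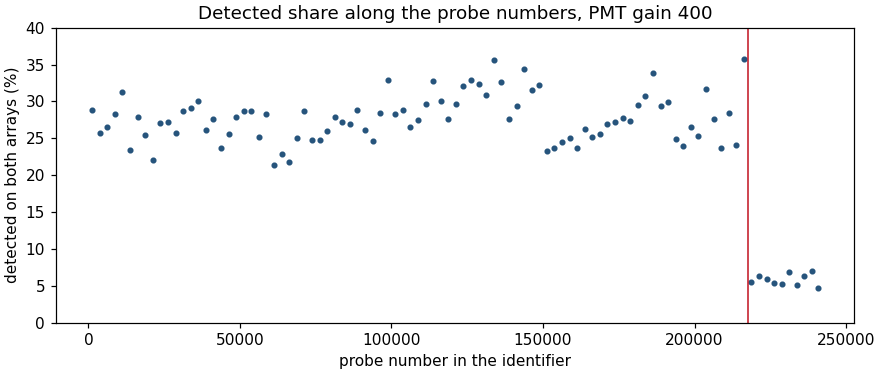
Percentage of target probes detected on both arrays at PMT gain 400 (vertical axis) against the probe number in the identifier (horizontal axis), 1 point per bin of 2500 numbers (1399 in the last bin), with a red line at the step. Bins wholly before the line lie between 21.4% and 35.6%, bins after it between 4.72% and 6.96%, and the bin that holds the line is at 35.8%.

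The next comparison set array 2 against array 1, to see how closely a second hybridisation of the same RNA repeated the first. On normalised log2 intensity over all 241399 target probes, Pearson's r was 0.966 and Spearman's rho 0.761 at gain 400, and 0.965 and 0.758 at gain 500. These are correlations across probes, which are not independent replicates. The SD of a probe on 1 array was 0.26 log2 at both gains, and 98.6% and 98.5% of probes lay within 2-fold on the 2 arrays. These values depended on the processing, which gave all 4 scans a common distribution and added an offset of 50 before the log2. The likeness of the SD at the 2 gains was thus partly built in. The SD at gains 400 and 500 was 0.14 and 0.14 log2 without background correction, with 99.9% of probes within 2-fold at both gains, and 0.17 and 0.36 with median centring or no normalisation. It was 0.77 and 0.78 with plain subtraction, over the 193388 probes above 0. With the series matrix values, without normalisation and over 220623 and 208358 probes, it was 0.75 and 0.88, with 77.7% and 74.2% of probes within 2-fold. Among probes detected on both arrays r rose to 0.987 and 0.985 and rho to 0.970 and 0.969, with an SD of 0.19 and 0.20 log2. Of the probes detected on array 1, 87.3% at gain 400 and 87.6% at gain 500 were also detected on array 2.

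The error fell slowly with brightness. When probes detected on both arrays and saturated on neither were put into 4 groups of about equal size by background-subtracted intensity at gain 400, the median absolute log2 difference between arrays, about its group's median, went from 0.23 in the dimmest group, with a median intensity of 70.5, to 0.19 in the brightest, with a median of 998.5. At gain 500 the corresponding values were 0.24 and 0.19. The differences followed position on the slide: the median difference, array 2 minus array 1, in tiles of 20 by 27 spots ran from −0.35 to 0.43 log2 between the 5th and 95th percentile of 460 tiles at gain 400, and from −0.36 to 0.44 at gain 500. Removing each tile's median took away 44.2% of the variance of the difference at gain 400 and 43.9% at gain 500.

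**Figure D2:**
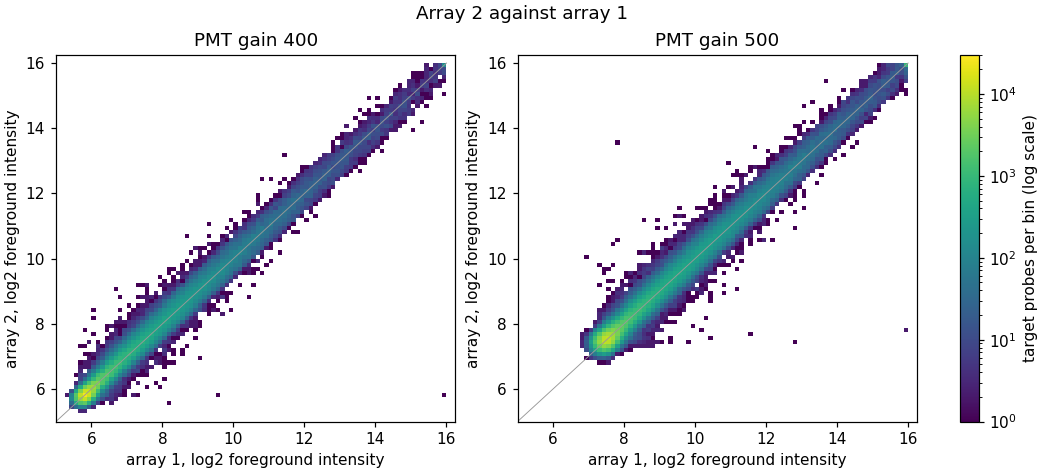
Log2 median foreground intensity of target probes on array 2 (vertical) against array 1 (horizontal), without background correction or normalisation, at PMT gain 400 (left) and 500 (right); colour gives the number of probes per bin on a log scale and the grey line marks equal values. Without background correction Pearson's r across the quantile-normalised probes was 0.990 at both gains.

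**Figure D3:**
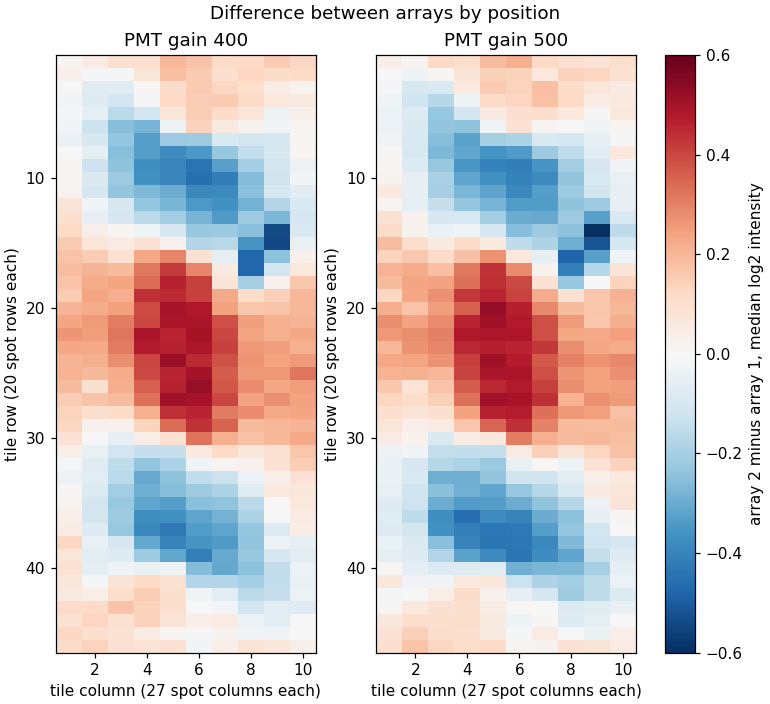
Median log2 difference in intensity, array 2 minus array 1, for each tile of 20 spot rows by 27 spot columns, over probes detected in all scans, at PMT gain 400 (left) and 500 (right). Red tiles were brighter on array 2 and blue tiles on array 1, and the extremes at gain 400 were −0.54 and 0.52.

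A few probes stood far apart between arrays at both gains. TA3-044721 read 65238 on array 1, at the scanner ceiling, against 18 on array 2 at gain 400, and 64623, also at the ceiling, against 40 at gain 500. At gain 500 it passed the detection rule on neither array. The neighbouring spot TA3-032447 had a foreground of 771 on array 1 and 54 on array 2 at gain 400. TA3-022258 went the other way, with 60 on array 1 and 485 on array 2 at gain 400 and 252 and 2255 at gain 500. In all, 6 target probes differed by more than 4-fold between arrays in the same direction at both gains, and 208 by more than 2-fold.

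Raising the gain from 400 to 500 made the probes 4.86 ± 0.0164-fold brighter (SD, n = 2), or 2.28 ± 0.005 on the log2 scale, over probes detected in both scans of an array and saturated in neither. The slope of log2 intensity at 500 on that at 400 was 1.01 ± 0.004 (SD, n = 2). The local background rose as well, from a median of 43 on both arrays to 131, and its SD from 23 to 117 on array 1 and 118 on array 2. GenePix's signal-to-noise score had a median over target probes of 1.05 and 1.09 on arrays 1 and 2 at gain 400 and of 0.897 and 0.913 at gain 500. The number of arrays limits the precision of all these values.

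The higher gain brought more spots to the ceiling of 65535. The median foreground was saturated in 170.5 ± 4.95 target spots (SD, n = 2) at gain 400 and 993.5 ± 19.1 (SD, n = 2) at gain 500. Spots with any saturated pixel numbered 256 and 274 on arrays 1 and 2 at gain 400, and 1372 and 1446 at gain 500. Those with only some pixels at the ceiling are not counted as saturated here or below. On both arrays 154 probes were saturated at gain 400 and 926 at gain 500, and all 154 were among the 926. The 10 brightest probes that were unsaturated at gain 400 were all saturated on both arrays at gain 500. Among these were TA3-100612, at 61683.5 ± 1175 (SD, n = 2) at gain 400, and TA3-129391, at 59857.5 ± 622 (SD, n = 2). No fold between gains is given for them, because their values at gain 500 are bounded by the ceiling.

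**Figure D4:**
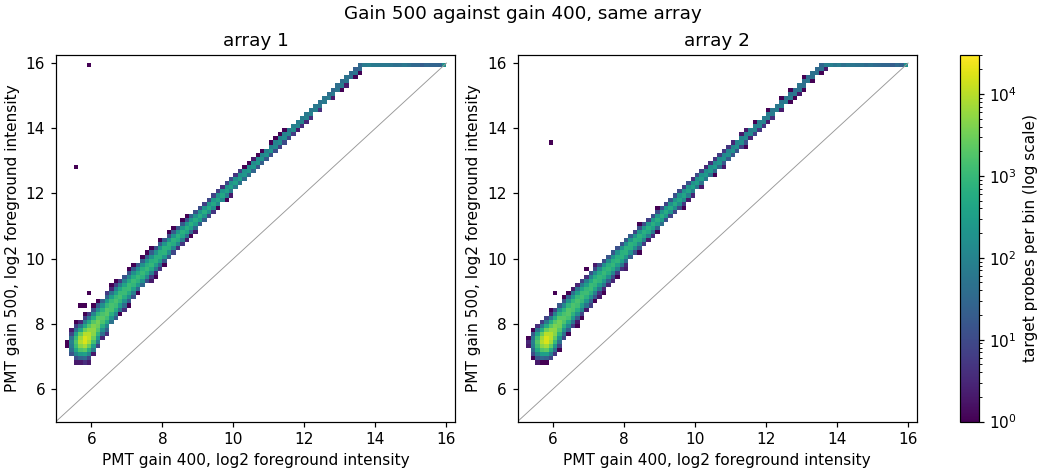
Log2 median foreground intensity of target probes at PMT gain 500 (vertical) against gain 400 (horizontal) for array 1 (left) and array 2 (right); colour gives the number of probes per bin on a log scale and the grey line marks equal values. The flat upper edge at gain 500 is the ceiling of 65535, reached by 1007 target spots on array 1 and 980 on array 2.

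A last test between gains looked for probes whose signal relative to the other probes changed with the gain. With quantile-normalised values and the array as a block, limma called 813 of 241399 probes at an adjusted p under 0.05, 440 higher and 373 lower at gain 500, and 371 of them changed by more than 1.5-fold, 144 higher and 227 lower. Without background correction 186 calls changed by that much, 3 higher and 183 lower. Of the 813, 746 (91.8%) were saturated in at least 1 scan and the other 67 in no scan, while 1061 of all target probes were saturated in at least 1 scan. Of the 440 higher calls, 412 were saturated at gain 500 only. Of the 373 lower calls, 149 were saturated at gain 500 only and 185 at both gains. The median intensity at gain 400 was 16714.75 over the higher calls and 58834.5 over the lower ones. The values of these saturated calls at gain 500 were bounded by the ceiling on at least 1 array. Their direction and size therefore cannot show that their signal changed relative to the other probes. Among the 813, 704 moved the same way on both arrays and the rest did not. When the saturated probes were left out of the fit, 2 probes were called, TA3-108412 and TA3-205207, so calls were also lost among probes that stayed in it. With median centring in place of quantile normalisation 61217 probes were called, 97.8% of them higher at gain 500, against 54.1% in the main setting. Over probes detected in both scans and saturated in neither, the slope between gains was 1.13 with normexp, against 1.01 with plain subtraction. Median centring does not remove a slope, so these calls need not be particular to single probes. Whether the slope made them was not tested. With the series matrix values 8020 were called, 87.8% of them higher. Among probes detected in all 4 scans 314 were called, 38.2% of them higher. Without the block, or without the trend of the variance on intensity, limma called 0 probes, with 6360 and 12168 at an unadjusted p under 0.05. With the array as a block, the p-values measure how the change between gains differed over 2 arrays of 1 RNA pool. Probes of like intensity shared a variance, so a probe's own disagreement between arrays did not widen its SE. TA3-011588 changed by 8.75 log2 on array 1 and 0.45 on array 2, yet had an SE of 0.087.

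Of the 5 largest relative rises, the first 3 came from 1 array each. The other 2 rose on both arrays, 1 in a probe that was saturated on both arrays at gain 500 and 1 in a dim probe detected in no scan. The saturated probe, TA3-026529, changed by 1.13 log2 in the main setting. With the series matrix values it changed by 0.0767 log2 and was not called. It stayed called without background correction, at 0.483 log2, with median centring, at 0.906, and with plain subtraction floored at 1, at 1.13. Its values at gain 500 were bounded by the ceiling, so these sizes cannot show a rise in its signal. TA3-011588 read 2 and 9 on arrays 1 and 2 at gain 400, and 65346, at the ceiling, on array 1 against 105 on array 2 at gain 500. TA3-205207 read 13 and 16 at gain 400, and 96 on array 1 against 12131 on array 2 at gain 500. It passed the detection rule in no scan. Of the 5 largest falls, 3 were in probes saturated in all 4 scans, for which no fold is given, and the first 2 were in dim probes. TA3-229886 read 35 and 27 at gain 400 and −92 and −46 at gain 500, and TA3-052574 read 34 and 33 at gain 400 and −80 and −3 at gain 500. Without background correction neither of these falls was called, with limma adjusted p of 0.988 and 0.974, and the dim rise on both arrays was not called either, with 0.03 log2 in place of 1.13 and a limma adjusted p of 0.998. With saturated probes left out, the dim rise of 1.13 log2 and the falls of −1.33 and −1.18 log2 were as before, but limma's adjusted p went to 0.232, 0.744 and 0.650. With plain subtraction floored at 1 the 3 changes were 5.32, −6.41 and −6.53 log2, with a limma adjusted p of 0.967 for each. Their size thus rested on the background correction.

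The control probes ranged from background to the scanner ceiling. The 10 spike-in control names beginning with E1A, at 60 spots each, had medians at gain 400 from 14.5 ± 0.707 (E1A_r60_3, SD, n = 2) to 26332.5 ± 4618 (E1A_r60_1, SD, n = 2), and 6 of the 10 lay above the negative control mean + 3 SD in all 4 scans. The dimmest of these 6 was E1A_r60_a20, at 78.75 ± 6.01 (SD, n = 2). E1A_r60_a135, at 34.0 ± 2.83 (SD, n = 2), did not pass in any scan. The negative controls had a median of 12.5 ± 0.707 (SD, n = 2) at gain 400 and 44.5 ± 2.12 (SD, n = 2) at gain 500. Bright corner spots had a median of 270 ± 41.0 (SD, n = 2) and dark corner spots 13 on both arrays at gain 400. E1A_r60_1 was saturated in all 60 spots on both arrays at gain 500. Array 2 read lower than array 1 for the 6 brightest names at gain 400, with ratios from 0.779 to 0.898. Other controls read higher on array 2 at gain 400, with ratios of 1.24 for the bright corner, 1.20 for DCP_1_0, 1.49 for DCP_1_4, 1.42 for DCP_1_7 and 1.39 for ETG05_36762, while DCP_1_1, at 0.857, and DCP_20_3, at 0.794, read lower. Whether RNA matching the E1A probes was added is not given in the sources used here, so their values have no dose.

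**Figure D5:**
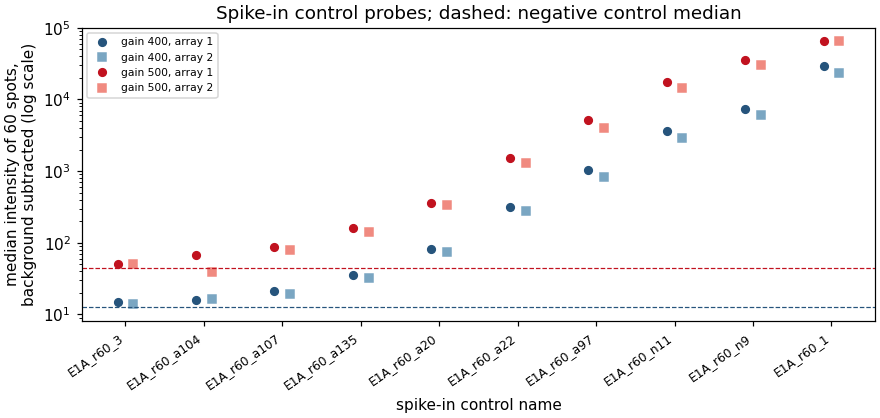
Median background-subtracted intensity of the 60 spots of each spike-in control name (log vertical axis) in each of the 4 scans, circles for array 1 and squares for array 2, blue for PMT gain 400 and red for gain 500. Dashed lines give the negative control median, 12.5 at gain 400 and 44.5 at gain 500.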

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

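The comparison of the remaining control names with the negative controls was chosen after the data had been seen, and no explanation was tested for it. Of the control names outside the classes planned for comparison, 13 had medians above the negative control mean + 3 SD in all 4 scans, against a negative control median of 12.5 at gain 400. All values here are means of 2 array medians at gain 400. The control DCP_1_0 read 35031.5, DCP_1_1 read 23854.5, DCP_1_2 read 18329.5, DCP_1_4 read 11075 and DCP_1_7 read 6293.5, while DCP_1_11 read 16.5 and did not pass. DCP_22_0 read 374.5, DCP_22_2 read 281.5, DCP_22_4 read 128 and DCP_22_6 read 63.5. DCP_20_0 read 95.5, DCP_20_1 read 74.5 and DCP_20_3 read 61. Each of these names had 3 spots per array. Of the 18 names beginning with DCP, 12 passed in all 4 scans. Besides DCP_1_11, those that did not were DCP_20_5 at 39.5, DCP_20_7 at 16.5, DCP_20_9 at 15.5, DCP_22_7 at 30 and DCP_22_9 at 18. Among the 13 control names beginning with ETG, at 40 spots each, ETG05_36762 read 117.75 and was the only 1 to pass, while the lowest of the others read 11.75. The names are as the files give them, and what these controls were designed to bind is not given in the sources used here.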

How the results depend on the processing

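The foreground-only detection rule, the count of probes up to the step and the removal of tile medians were chosen after the data had been seen; every other alternative was planned. The cause of a change was not tested unless stated. Under 8 alternatives, detected probes at gain 400 ran from 49688 with 3 SD to 92498 with the foreground-only rule, against 61715 in the main rule. Keeping flagged spots was among these 8 and could not differ, because 0 spots were flagged. At gain 500 the count ran from 47731 to 93444 with the same 2 rules. Under the foreground-only rule the order of the gains thus turned for these counts of detection on both arrays. The mean difference of shares between gains was −0.911 points with 3 SD, −0.286 with the negative control threshold, −0.0992 with the foreground-only rule (1.43 on array 1 and −1.63 on array 2) and −2.14 with at least 1 array, and on single arrays in the main rule it ran from −1.90 to −1.34. Pearson's r between arrays at gains 400 and 500 was 0.990 and 0.990 without background correction, 0.888 and 0.884 with plain subtraction, 0.987 and 0.985 over detected probes, 0.981 and 0.950 with either no normalization or median centring, 0.963 and 0.962 with pixel means, and 0.884 and 0.861 with the series matrix. Over detected probes with tile medians removed it was 0.992 and 0.991. The median log2 gain effect was 2.18 without background correction, 2.05 with normexp and 2.23 with no filter on dim probes, and 2.28 to 2.29 on single arrays. With pixel means 0 spots were saturated at either gain, since a mean over pixels stays under the ceiling. Without background subtraction the negative control medians were 55 and 177.

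Calls of the test between gains depended on the setting. With no replicate block limma called 0 probes, and 0 without the variance trend, with 6360 and 12168 at an unadjusted p under 0.05 against 12823 in the main setting. Median centring gave 61217 calls, of which 769 were among the 813, and the series matrix 8020, with 668 shared. Probes detected in all 4 scans gave 314, and leaving out saturated probes gave 2, although 67 of the 813 were not saturated. No background correction gave 968, of which 186 were over 1.5-fold against 371, and plain subtraction 844. Leaving out an array left no residual, so no count could be made, and the comparisons of probes of 1 target and of probe lengths were not run. The median signal-to-noise score was at most 1.09, and whether signal over background limits these results was not tested.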

Other observations

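The patterns here were found in the data, and the tests of slide position, of the kind of probe, of very bright spots and of the negative controls' correlation were chosen after the results they bear on had been seen. No biological explanation was tested for any of them, since the design gives none.

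The step in detection after TA3-217456 was weighed against 3 explanations. Slide position was argued against, because 27.8% of the earlier-numbered spots next to late-numbered ones were detected, against 5.90% of the late-numbered probes. The detection rule was argued against too, since the late share was at most 0.296 of the early share at gain 400 under the negative-control and foreground-only rules. The late-numbered probes may be another kind of probe or have another kind of target, but 0 columns give a length, sequence or target for them, so this stays open. Late-numbered probes also lay below the negative control median foreground more often at gain 400, at 43.02% and 44.6% on arrays 1 and 2 against 16.32% and 17.4% of the earlier ones.

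The bands in the difference between arrays were the same in both scans, with tile medians correlating at 0.987 between gains, which argues against a single scan or its quantification. The first test of local background, whose bounds were set before its result was seen, did not decide, because background tile medians spanned 0.281 of the signal span, between those bounds. In a further test, chosen after that result, tile medians of 10741 spots at least 20 times their background spanned 1.06 times the span of all detected spots. This argues against local background in such spots and leaves it open in dimmer ones. Spots of E1A_r60_n9, E1A_r60_n11, E1A_r60_a97 and E1A_r60_a22, for which added RNA is not stated, followed the bands with r = 0.891 over 240 spots. Any effect of slide position on bright spots would give this. The test therefore cannot single out uneven hybridisation or washing, which stays a candidate explanation. On single arrays the r of these controls with the bands ran from 0.672 to 0.744 on array 2 and from −0.0515 to 0.0131 on array 1. In these spots the bands were thus seen on array 2 rather than array 1.

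Probes undetected in every scan still carried a repeatable signal, with a correlation of foreground between arrays of 0.678 at gain 400 (Spearman's rho 0.561) and 0.666 at gain 500. Background shared by position was argued against, as negative controls correlated at 0.111 at gain 400. Weak binding, specific or not, may contribute, since 11.1% of the 151566 undetected probes lay above the negative controls' 99th percentile, a foreground of 64, on both arrays. For the negative controls the share was 0%, which was nearly fixed in advance because the percentile was their own. Among the early-numbered undetected probes 12.2% lay above it on both arrays, and among the late-numbered ones 4.32%.

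Across target spots, local background correlated at 0.0282 between arrays at gain 400, and at 0.0349 between the 2 scans of array 1. Since even 2 scans of 1 array hardly agreed, these single-spot values cannot show whether background is shared between arrays. Log2 foreground of consecutively numbered probes up to the step correlated at 0.0316 on array 1. In quantile-normalised signal, where the general rise with the gain is removed, jumps over 4-fold between gains on 1 array, with under 2-fold on the other, occurred in 3 probes. These were TA3-011588 and TA3-108412 on array 1 and TA3-205207 on array 2. On the same scale 0 probes jumped so on both arrays.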
